A study of Mus musculus with 12 samples.

How the data were processed

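MicroRNAs were measured in LLC1 cells, a cultured mouse Lewis lung carcinoma line, on Agilent 1-colour microarrays with 1 array per sample. Per the labels' protocols, total RNA was isolated with a mirVana kit and 100 ng of it was labelled with Cy3. The labels give 4 groups of 3 arrays: untreated control, a single dose of 2 Gy, a single dose of 10 Gy, and 5 fractions of 2 Gy (5x2 Gy, 10 Gy in total), with RNA taken 4 h after irradiation.

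The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers, the extraction protocol was the 1-colour miRNA protocol, and the processed signal equals the background-subtracted and spatially detrended signal. The deposited spot flags (control type, outlier, well above background, saturated) are 0 or 1 and were used as filters, per the file headers. The authors' deposited series table holds log2 values. Set against the scanner values, these were the log2 of the processed signal, with signals under 1 set to 1, shifted by 1 constant per array so that all column means equal 1.98. The shifts ran from -0.27 to 0.51 and the column medians from -0.19 to 1.14, with equality taken within 1e-04, so scale, centring and direction were all settled. The headers name mm9 as the build of the array design, and the reference table of genes is of assembly GRCm38.p6, so no coordinates are given. That table served for names and neighbouring genes, and 106 of the 118 tested names matched it. Names are those of the array's design, so some carry an old release or a withdrawn-name tag (22 of the 576 entries, 5 of them tested).

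Each array holds 12493 spots, of which 953 are controls. The other 11540 spots belong to 1712 probes, with 5 to 20 spots per probe and 1 to 5 probes per miRNA. They cover 576 entries, 566 of mouse and 10 of herpesviruses. Control spots and outlier spots (2.04 to 4.95% of spots per array) were left out, and 0 spots were saturated. Spots of a probe were averaged. Each array was divided by its 75th percentile over the 78 probes detected on all arrays. A floor of 0.0598 of that percentile (log2 -4.06) was then set, and log2 was taken. A probe was detected on an array when over 0.5 of its spots were well above background. A miRNA's level was the mean of its probes detected on at least 3 arrays (90 tested miRNAs had several probes and 28 had 1). A miRNA was tested when detected on all 3 arrays of at least 1 group, which left 118 of 576; 48 were detected on all 12 arrays. Of the 118, 71 lay above the floor on all arrays and 19 at the floor on all arrays. A change of a miRNA that was not well above background on any array of 1 group is only a bound. The bound is the other group's mean against the lowest detected signal of the dim arrays, and no fold is given where that bound is under 1. No 2 arrays held identical values, and 0 columns of other samples were present.

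Groups were compared with limma 3.58.1 in R 4.3.3 (files read with version 1.17.8 of data.table) on all 12 arrays, which share 1 estimate of the spread (8 residual and 0.45 prior degrees of freedom), with no covariates. Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. The comparisons were each irradiated group minus control, 5x2 Gy minus 10 Gy, 10 Gy minus 2 Gy, 5x2 Gy minus 2 Gy, and an F test over the 4 groups. Comparisons that share arrays are not independent, so no overlap of their calls is given. Levels and changes are log2 values, and intervals are at 95%. The number of arrays limits the precision.

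Of 16 fixed lists, 9 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01. These were p53-responsive miRNAs, the miR-17 family clusters, the let-7 family, regulators of the DNA damage response, inflammation and interferon response, the miR-15/16 and miR-29/30 families, miRNAs oncogenic or abundant in carcinoma lines, fibroblast and endothelial markers, and entries often traced to rRNA, tRNA or repeats or GC-rich with high array background. The other lists were the miR-200 family, the Sfmbt2 intron cluster, the Dlk1-Dio3 cluster, blood cell markers, muscle markers, nerve cell and liver markers, and herpesvirus entries. Of the entries on the array, tested or not, 4 of 13 in the p53 list stood in another list too. So did 2 of 17 in the miR-17 clusters, 0 of 9 in let-7 and 9 of 24 in the damage response. The shares were 7 of 16 in inflammation, 8 of 13 in miR-15/16 and miR-29/30 and 4 of 18 in the carcinoma list. They were 2 of 9 in the fibroblast list and 1 of 11 in the rRNA and GC-rich list.

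The groups, comparisons, lists and main settings were fixed before the data were examined, as was the rule for naming miRNAs. Among called miRNAs whose groups did not overlap, the rule named up to 12 with the largest rise and up to 12 with the largest fall, in each comparison with control and in 5x2 Gy minus 10 Gy. Where under 5 passed, the 5 with the smallest p were added, and the other 2 comparisons took the 5 with the smallest p. Members of the fixed lists may be named with their list. The miRNAs miR-34a-5p, miR-34c-5p, miR-21a-5p, miR-155-5p, miR-146a-5p, let-7a-5p, miR-17-5p (on the array as miR-17_v17.0) and miR-210-3p were always named where detected.

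The files place the arrays on 2 slides. Slide 1 held all control and 2 Gy arrays and 10 Gy replicates 1 and 2 (8 arrays), and slide 2 held 10 Gy replicate 3 and all 5x2 Gy arrays (4 arrays). Slide was tried as a fixed block, as a random block and as slide 1 alone. The other alternatives were normexp background correction, other scalings, other floors, filters and probe summaries, the authors' deposited log2 table, covariates, other spread estimates, a replicate block, fry, camera with an estimated correlation, and leaving out each array. Normexp was run on the median signal and median background of each spot. Without each array, values were processed anew, so a change can move without an array outside its groups. The steps were tested on values simulated from the arrays' own means and spread, with each miRNA varying independently. For 5x2 Gy minus control, with 118 miRNAs, 30 of them changed, and 50 simulations, 23.6% of changes of 0.25 log2 were recovered, 54% of 0.5 and 81% of 1, with 3.6% false among the calls. With no change simulated, camera called 0.02 lists and limma 0.1 miRNAs per simulation. Changes were placed only in miRNAs with a mean over 0.5 log2 above the floor. On the real arrays the lists' estimated correlations ran up to 0.68, so these rates of false calls need not hold there. Correlations across arrays used 100000 permutations and seed 11; comparisons of 1 value between groups used exact permutation.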

Results

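The arrays measured microRNA levels in LLC1 Lewis lung carcinoma cells, a mouse lung tumour line, 4 h after ionizing radiation. Control cells, cells given a single dose of 2 Gy or 10 Gy, and cells given 5 fractions of 2 Gy (5x2 Gy) were on 3 arrays each. The 2 groups with 10 Gy in total received the same dose at once or in fractions. The labels call the 3 arrays of a group biological replicates, and name no shared culture or day. Levels below are log2 values relative to the array's 75th percentile, and a change is a difference of group means with n = 3 against 3.

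Between 48 and 137 miRNAs were detected per array out of 576 entries. The mean number was 74 ± 25.5 in control (SD, n = 3), 84.3 ± 22.7 after 2 Gy, 83.3 ± 28 after 10 Gy and 127 ± 8.9 after 5x2 Gy. Exact permutation of 5x2 Gy against each other group gave a two-sided p of 0.1, the smallest that 3 arrays against 3 allow; among the other groups it gave 0.6, 0.7 and 1. The number followed array brightness, the percentile used for scaling, which ran from 110.5 to 1102 (r = 0.96, rho = 0.96, permutation p = 1e-05 for both, the smallest possible, and 8e-05 adjusted over 8 relations). Without the 2 arrays farthest from the median brightness r was 0.98, and among the 8 arrays of slide 1 it was 0.95 (exact permutation p = 0.000422). All control and 2 Gy arrays and 10 Gy replicates 1 and 2 were on slide 1. All 5x2 Gy arrays and 10 Gy replicate 3 were on slide 2.

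**Figure D1:**
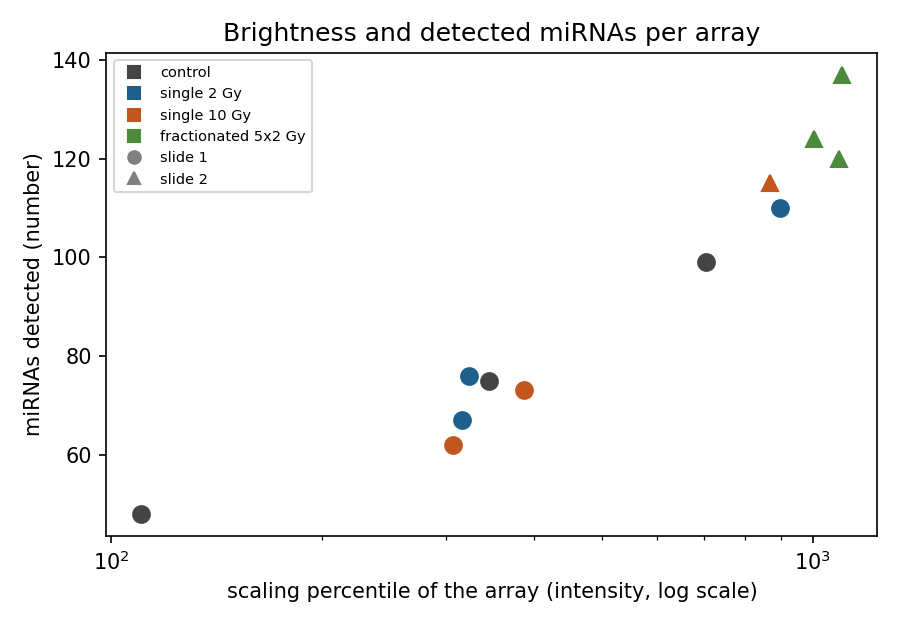
Number of miRNAs detected (vertical axis) against the scaling percentile of processed signal in scanner units (horizontal axis, log scale), 1 point per array, 12 arrays in 4 groups. Brighter arrays detected more miRNAs, from 48 to 137, and the 5x2 Gy arrays had a mean of 127.

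Several families had no tested member. None of the 9 miR-200 family entries, 24 entries of the Sfmbt2 intron cluster, 5 matched blood cell markers, 7 muscle markers, 8 nerve cell and liver markers or 10 herpesvirus entries was detected on all arrays of a group. The blood cell list names miR-142-3p and miR-142-5p, and the array holds miR-142a-3p and miR-142a-5p, which were not matched to it. Both were tested and did not pass (limma F test adjusted p = 0.779 and 0.851), so blood cell markers were not absent as a whole. The Dlk1-Dio3 cluster, an imprinted miRNA cluster, had 1 tested member of 45 entries, miR-494-3p, with changes of -1.06 after 2 Gy, -1.61 after 10 Gy and -1.02 after 5x2 Gy, none passing. MiR-34a-5p, a p53 target, was not well above background on any array.

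The comparison of 2 Gy with control asks what the lowest single dose changed. No single miRNA passed: limma called 0 of 118, against 11 at an unadjusted p under 0.05 (6 higher, 5 lower). The smallest p belonged to miR-92a-3p, a member of the miR-17 family clusters (change -0.31), miR-107-3p (0.13) and miR-34b-5p (0.55, SE 0.14, 1.46-fold), each with a limma adjusted p of 0.142. MiR-21a-3p (-0.47, limma adjusted p = 0.243) and miR-322-5p (0.29, limma adjusted p = 0.261) came next. MiR-21a-3p was detected on 1 of 3 arrays of each group and sat at the floor on 2 arrays of 2 Gy, so its size depended on the floor: it was -0.77 with a floor 4 times lower and -0.89 to -0.20 with 1 array left out. It passed with the brightest probe (-0.65, limma adjusted p = 0.0115; 0.0115 to 1 over its alternatives), with quantile scaling (-0.30) and with the mean of the rRNA and GC-rich list as a covariate (-0.66). The sign of miR-92a-3p turned with the authors' deposited log2 values (0.07), and that of miR-107-3p with normexp background correction (-0.15 and -0.03 with offsets of 50 and 1). MiR-34b-5p passed with array brightness as a covariate (0.63, limma adjusted p = 0.018; 0.00118 to 1 over its alternatives) and changed by 0.22 with normexp at an offset of 50. MiR-34c-5p (0.71, limma adjusted p = 0.611) also passed with brightness (1.05, limma adjusted p = 0.00797; 0.00797 to 1 over its alternatives), and changed by 0.12 with the mean of the rRNA and GC-rich list as a covariate. With 1 array left out it ran from 0.47 without control replicate 3 to 1.11 without 2 Gy replicate 2.

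As groups, 3 lists moved after 2 Gy by camera. The p53-responsive list was higher, with a mean change of 0.19 and a median of 0.07 (camera adjusted p = 0.0156; adjusted p = 0.169 with an estimated correlation). None of its 8 members passed, and 2 were higher adjusted over the list alone, miR-34b-5p and miR-107-3p. The mean rests largely on miR-34b-5p (0.55) and miR-34c-5p (0.71), whose genes are neighbours, while miR-34b-3p and miR-34c-3p sat at the floor on all arrays. Arrays left out aside, the call was kept in 6 of 15 other settings. It ended with median scaling, quantile scaling, no scaling, brightness as a covariate and normexp at both offsets. The median of the p53 list turned with normexp (-0.16 and -0.06). The miR-17 family clusters, tied to cell proliferation, were lower, with a mean of -0.15 (camera adjusted p = 0.0151; adjusted p = 0.405 with an estimated correlation). None of 12 members passed and 1 was lower adjusted over the list alone, miR-92a-3p. The call was kept in 9 of 15 other settings. It ended with all probes, without scaling, with quantile scaling and with normexp at an offset of 50. With the mean of the rRNA and GC-rich list as a covariate the median was -0.03 and the call ended too (camera adjusted p = 0.777; 0.00169 to 0.855 over its alternatives), as did that of the p53 list (median 0.11, camera adjusted p = 0.195; 0.02 to 0.329). The list of rRNA, tRNA, repeat and GC-rich entries, a sign of background or RNA state, was lower, with a mean of -0.77 (camera adjusted p = 0.00253; adjusted p = 0.298 with an estimated correlation). All 6 tested members were negative (miR-690, miR-709, miR-720_v18.0, miR-1224-5p, miR-188-5p and miR-494-3p), and 0 passed in either adjustment. Both groups lay wholly on slide 1, so these values are also the blocked and within-slide values (blocked camera adjusted p = 0.02, 0.00892 and 0.00468). Of the other lists, the DNA damage response had a negative mean of -0.02 and a camera direction of higher, and inflammation a median of 0.04 against a mean of -0.0031. Without control replicate 2, 3 or 2 Gy replicate 2, limma called 6, 2 and 1 miRNAs, and without control replicate 1 camera called 0 lists. Leaving out the scaling raised the changes of the 49 miRNAs above the floor together, by 0.59 in the median, and miR-92a-3p (0.28) and the median of the miR-17 clusters (0.33) turned with that common shift. Quantile scaling called 2, 1 of them higher.

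The comparison of 10 Gy with control asks the same of a high single dose. MiR-34b-5p rose, from -1.74 ± 0.11 in control to -0.89 ± 0.09 (SD, n = 3), a change of 0.85 (95% interval 0.54 to 1.17, SE 0.14, 1.81-fold, limma adjusted p = 0.0239). It is transcribed with miR-34c under p53, and the genes Mir34b and Mir34c are neighbours with 0 genes between them in assembly GRCm38.p6. MiR-34c-5p changed by 1.06 (SE 0.42), with a limma adjusted p of 0.236 (blocked 1.36, 0.183), and did not pass. It passed with array brightness as a covariate (1.44, limma adjusted p = 0.000978; 0.000978 to 1 over its alternatives) and with scaling over all probes, which raised miRNAs above the floor together (1.56, limma adjusted p = 0.00306), and changed by 0.34 with the mean of the rRNA and GC-rich list as a covariate. The next smallest p belonged to miR-129-2-3p (0.75), miR-107-3p (0.13) and miR-92a-3p (-0.29), each with a limma adjusted p of 0.103, and miR-720_v18.0 (-0.62, limma adjusted p = 0.14). MiR-129-2-3p was detected on 1 of 3 control arrays. It was 1.15 with a floor 4 times lower, with no change left when the floor was doubled, and 0.38 to 1.02 with 1 array left out. It passed with array brightness as a covariate (0.81, limma adjusted p = 0.0269; 0.014 to 0.971 over its alternatives), with only the 2 groups compared in the fit, and without 2 Gy replicate 2. MiR-92a-3p turned with the authors' deposited log2 values (0.20). With normexp at an offset of 50, miR-129-2-3p (-0.13) and miR-107-3p (-0.15) turned too.

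Limma called 1 of 118 miRNAs after 10 Gy, against 24 at an unadjusted p under 0.05 (15 higher, 9 lower). With array brightness as a covariate it called 26, 14 of them higher and 12 lower. With slide as a block miR-34b-5p changed by 0.89 (limma adjusted p = 0.0879), and within slide 1 by 0.89 (limma adjusted p = 0.358), so neither passed, nor did 0.45 with normexp at an offset of 50 (limma adjusted p = 0.424); over its alternatives the adjusted p ran from 0.000174 to 0.971. Its call ended without control replicate 1, 10 Gy replicate 2 or 3, or any of the 5x2 Gy replicates, which left 0 calls. Without 2 Gy replicate 2 or 10 Gy replicate 1 there were 2 calls, without control replicate 3 there were 4, and without control replicate 2 there were 8. Quantile scaling called 4 miRNAs, 3 of them higher. Normexp called 2 with an offset of 50 and 1 with an offset of 1, all lower and none of them miR-34b-5p. Scaling over all probes and leaving out the scaling raised the changes of miRNAs above the floor together, by 0.49 and 0.65 in the median. MiR-92a-3p (0.20 and 0.36) and, without scaling, miR-720_v18.0 (0.03) turned with that common shift.

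**Figure D2:**
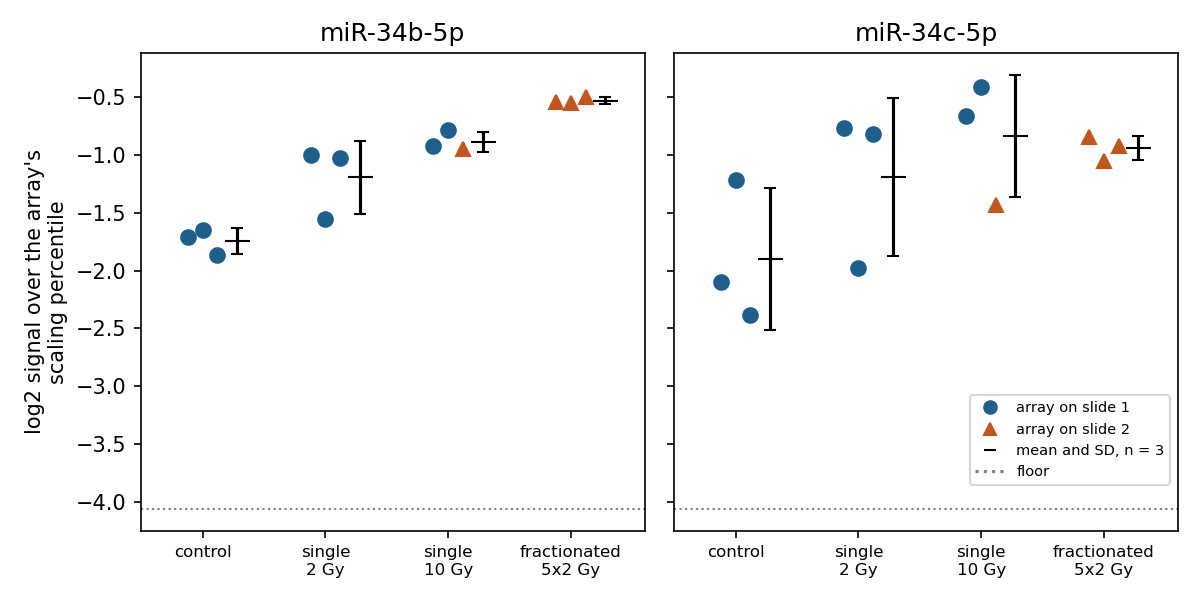
Levels of miR-34b-5p and miR-34c-5p (log2, relative to the array's 75th percentile) on each array by group; circles are slide 1, triangles slide 2, bars the mean and SD (n = 3), and the dotted line the floor. Mean miR-34b-5p was -1.74 in control, -1.19 after 2 Gy, -0.89 after 10 Gy and -0.53 after 5x2 Gy, while control arrays spread more for miR-34c-5p (-1.90, SD 0.61). Higher means than control held under each scaling tried.

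Camera moved 4 lists after 10 Gy. The miR-17 family clusters were lower (mean -0.25, camera adjusted p = 0.00249, blocked and within slide 1 -0.32 with 0.000324; adjusted p = 0.217 with an estimated correlation). None of 12 members passed and 1 was lower adjusted over the list alone, miR-92a-3p. The call ended with all probes and without scaling, where the median turned with the common shift (0.15 and 0.27). With the mean of the rRNA and GC-rich list as a covariate the median was -0.15 and the call ended too (camera adjusted p = 0.498; 0.000247 to 0.512 over its alternatives). The let-7 family, regulators of differentiation, was higher (mean 0.15, camera adjusted p = 0.00273, blocked and within slide 1 0.18 with 0.00996; adjusted p = 0.217 with an estimated correlation), with 0 of 9 members passing in either adjustment. Its median turned with the mean of the rRNA and GC-rich list as a covariate (-0.06, camera adjusted p = 0.981; 0.000441 to 0.981 over its alternatives). The call was kept in 11 of 15 other settings. Fibroblast and endothelial markers were higher (mean 0.18, camera adjusted p = 0.0475, blocked and within slide 1 0.21 with 0.0565; adjusted p = 0.217 with an estimated correlation). None of 5 passed and 2 did adjusted over the list alone, miR-214-3p (0.38) and miR-199a-3p (0.36). The median turned with normexp (-0.02 and -0.08), and only 2 of 15 other settings kept the call. The rRNA and GC-rich list was lower (mean -0.94, camera adjusted p = 0.00273, blocked and within slide 1 -1.06 with 0.00996; adjusted p = 0.217 with an estimated correlation), with 0 of 6 passing and 1 adjusted over the list alone, miR-720_v18.0. In the p53 list 1 of 8 rose, with 2 adjusted over the list alone (miR-34b-5p and miR-107-3p), and the list did not pass (camera adjusted p = 0.0676). The carcinoma list had a median of 0.03 and a mean of 0.04 but a camera direction of lower, and the damage response a mean of -0.03 and a camera direction of higher. The call for fibroblast markers ended without any 1 array except control replicate 2 (camera adjusted p 0.0485 to 0.277). Without control replicate 1 let-7 ended too (0.182), and 2 lists stayed.

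The comparison of 5x2 Gy with control asks what fractionated doses changed. Limma called 15 of 118 miRNAs, with positive differences for all 15. The count and its direction depended on the processing: scaling over all probes called 102 and no scaling 86, all higher, median scaling 2 higher, normexp 2 lower with an offset of 50 and 1 higher and 4 lower with an offset of 1, and the mean of the rRNA and GC-rich list as a covariate 29 higher and 12 lower. MiR-34b-5p rose from -1.74 ± 0.11 to -0.53 ± 0.03 (SD, n = 3), a change of 1.21 (95% interval 0.90 to 1.53, SE 0.14, 2.32-fold, limma adjusted p = 0.000888). MiR-129-2-3p was higher too (1.03, SE 0.18, limma adjusted p = 0.00743), but it was detected on 1 of 3 control arrays, whose mean of -4.00 lay near the floor of -4.06, so no fold is given. Its size depended on the floor, with 0.09 when the floor was doubled (limma adjusted p = 0.204; 0.000254 to 0.59 over its alternatives) and 1.43 with a floor 4 times lower. Leaving out 1 array at a time gave 0.62 to 1.3. MiR-34c-5p did not pass (0.96, SE 0.42, limma adjusted p = 0.161; blocked 1.86, 0.313). It passed with array brightness as a covariate (2.01, limma adjusted p = 0.000308). Along with most miRNAs, it also passed with the authors' deposited log2 values (2.41, limma adjusted p = 0.00173), with scaling over all probes (2.60) and without scaling (2.79). Its limma adjusted p ran from 3.48e-05 to 0.878 over its alternatives, and it changed by 0.47 with the mean of the rRNA and GC-rich list as a covariate.

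Smaller rises, each of them under 1.5-fold, included miR-214-3p (0.46), miR-26a-5p (0.44), miR-25-3p (0.40), miR-30b-5p (0.39), miR-199a-5p (0.33), miR-24-3p (0.32), miR-125a-5p (0.32) and let-7g-5p (0.24), with SE of 0.05 to 0.12 and limma adjusted p of 0.00623 to 0.0453. MiR-30b-5p was detected on 2 of 3 control arrays, and was 0.76 with a floor 4 times lower and 0.73, 0.74 and 0.84 without 5x2 Gy replicates 1, 2 and 3; miR-24-3p was 0.21 without control replicate 2. MiR-100-5p (0.23, SE 0.04, limma adjusted p = 0.00743) sat at the floor on 2 of the control arrays, so no fold is given. It was 0.94 with a floor 4 times lower (limma adjusted p = 0.0813; 0.000339 to 0.34 over its alternatives). No change was left with the floor doubled, which that range omits. With 1 array left out it ran from 0.03 to 0.51. MiR-30c-5p was not well above background on any control array and sat at the floor on all 9 arrays outside the 5x2 Gy group, so no fold is given (difference 0.26, SE 0.02, limma adjusted p = 8.93e-05). The SE rests on values set to the floor. Against the lowest signal well above background on the control arrays the difference was -0.63, so a rise is not established against that limit. Its size depended on the floor, with 0.97 when this was 4 times lower. With 1 array left out it was 0.81 to 0.86 in 6 of the fits, and no change was left in the others. Of the 15, 10 were detected on all 6 arrays. Limma found 36 at an unadjusted p under 0.05 (29 higher, 7 lower). The groups of 39 of 118 miRNAs (33.1%) did not overlap, where chance gives 10% for a miRNA taken alone. That share is no test, since miRNAs do not vary independently and the groups lay on different slides. A miRNA could also enter the 118 through the brighter 5x2 Gy arrays alone. MiR-29c-3p, of the miR-15/16 and miR-29/30 families, just missed (0.72, limma adjusted p = 0.0515).

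By list, 2 of 8 p53-responsive miRNAs rose, miR-34b-5p and miR-107-3p (0.20), and 2 adjusted over the list alone (camera adjusted p = 0.08). In the let-7 family 3 of 9 rose, let-7g-5p, let-7c-5p (0.22) and let-7i-5p (0.18), and 3 adjusted over the list alone (camera adjusted p = 0.08). Among regulators of the DNA damage response 3 of 16 were called, and 3 adjusted over the list alone (camera adjusted p = 0.104): miR-24-3p, which rose, and miR-30c-5p and miR-100-5p, whose control arrays lay mostly or wholly at the floor. In the miR-15/16 and miR-29/30 families 2 of 11 were called, and 3 adjusted over the list alone (camera adjusted p = 0.0519); miR-30b-5p rose, and miR-30c-5p was at the floor on all control arrays. Of the inflammation list 1 of 10 rose, miR-125a-5p, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.42). Of the carcinoma list 1 of 13 rose, miR-24-3p, and 0 adjusted over the list alone; its median of 0.13 and mean of 0.15 were positive while camera pointed lower (camera adjusted p = 0.922). In the miR-17 clusters 1 of 12 rose, miR-25-3p, also adjusted over the list alone (mean -0.0028, camera adjusted p = 0.381; blocked -0.21 with 0.00978, and adjusted p = 0.37 with an estimated correlation). Normexp at an offset of 50 turned the medians of the p53 (-0.34), damage response (-0.44), inflammation (-0.33) and miR-15/16 and miR-29/30 (-0.36) lists.

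Camera moved 2 lists after 5x2 Gy. Fibroblast and endothelial markers were higher (mean 0.30, camera adjusted p = 0.0397, blocked 0.38 with 0.0217; adjusted p = 0.244 with an estimated correlation). Of 5 members 2 rose, miR-214-3p and miR-199a-5p, and 3 adjusted over the list alone, with miR-199a-3p (0.35). The median turned with normexp at an offset of 50 (-0.17), and 5 of 14 other settings kept the call. The rRNA and GC-rich list was lower (mean -0.64, camera adjusted p = 0.0104, blocked -0.996 with 0.00978; adjusted p = 0.244 with an estimated correlation), with 0 of 6 passing in either adjustment. With all probes and without scaling, which moved the median of all miRNAs by 1.42 and 1.41, its median was 0.74 and 0.84, and camera still called it lower than the others (camera adjusted p = 2.95e-07 and 4.17e-06; 2.95e-07 to 0.327 over its alternatives, the highest with its own mean as a covariate, which removes the call by construction). With the mean of that list as a covariate the call of fibroblast markers ended (median 0.17, camera adjusted p = 0.186; 0.0172 to 0.514 over its alternatives). Without control replicate 1 camera called 0 lists. It called 1 without control replicate 3, 2 Gy replicate 2, 10 Gy replicate 3 or any 5x2 Gy replicate, and 4 without control replicate 2, 2 Gy replicate 1 or 3, or 10 Gy replicate 1 or 2.

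No slide held both groups, so a block for slide rests on the 10 Gy arrays. With it limma called 1 miRNA, miR-30c-5p (0.26, limma adjusted p = 0.0245). MiR-34b-5p changed by 1.31 (SE 0.26, limma adjusted p = 0.0748) and miR-129-2-3p by 1.15 (limma adjusted p = 0.254). The blocked values of the others were 0.71 for miR-214-3p, 0.43 for miR-25-3p, 0.33 for miR-30b-5p, 0.31 for miR-24-3p, 0.29 for miR-199a-5p, 0.25 for miR-26a-5p, 0.22 for miR-107-3p, 0.17 for miR-125a-5p, 0.10 for let-7g-5p and let-7c-5p, and 0.07 for miR-100-5p and let-7i-5p. Normexp with an offset of 50 turned miR-100-5p (-0.47), miR-125a-5p (-0.31), miR-129-2-3p (-0.46), miR-25-3p (-0.34), miR-30b-5p (-0.35), miR-30c-5p (-0.50), miR-214-3p (-0.18), miR-199a-5p (-0.17), let-7g-5p (-0.07) and miR-26a-5p (-0.02). MiR-34b-5p stayed positive with it (0.68, limma adjusted p = 0.11; 1.39e-05 to 0.11 over its alternatives), and with an offset of 1 it kept its call (0.97, limma adjusted p = 0.00704). Quantile scaling called 7, 6 of them higher. Without control replicate 1 the count was 6, without 10 Gy replicate 2 or 5x2 Gy replicate 2 it was 7, and without 5x2 Gy replicates 1 and 3 it was 8 and 9.

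**Figure D3:**
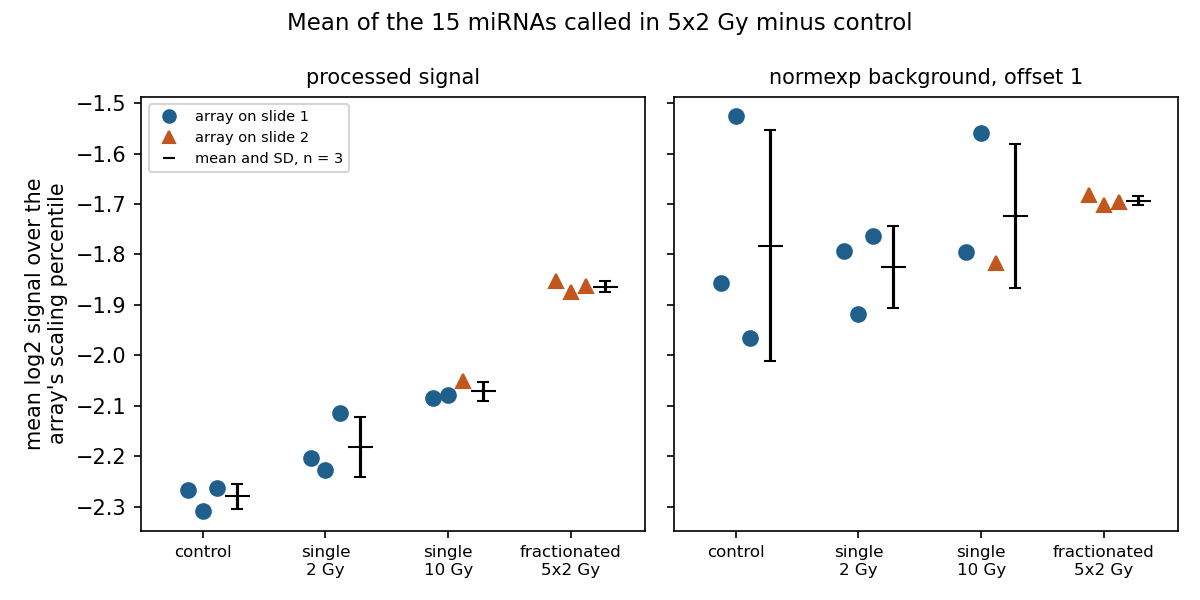
Mean level of the 15 miRNAs called in 5x2 Gy minus control (log2) on each array by group, from the processed signal and from normexp background correction with an offset of 1. With the processed signal the control arrays lay at -2.27, -2.31 and -2.26 and the 5x2 Gy arrays at -1.85, -1.87 and -1.86, while with normexp the control arrays lay at -1.86, -1.53 and -1.97 and the 5x2 Gy arrays at -1.68, -1.70 and -1.70.

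The comparison of 5x2 Gy with 10 Gy asks how fractionated and single irradiation differed at the same total dose. The groups also differ in the last dose given, 2 Gy against 10 Gy, and in the time since the first dose. A difference is thus not one of fractionation alone. Of 118 miRNAs limma called 3, with positive differences, miR-30c-5p (0.26, no fold, limma adjusted p = 8.93e-05), miR-125a-5p (0.29, SE 0.05, 1.23-fold, limma adjusted p = 0.0215) and miR-100-5p (0.20, SE 0.04, no fold, limma adjusted p = 0.047). MiR-100-5p was detected on 1 of 3 arrays of 10 Gy and sat at the floor on 2, and was 0.66 with a floor 4 times lower (limma adjusted p = 0.289; 0.000339 to 0.928 over its alternatives) and 0.03 to 0.34 with 1 array left out. MiR-30c-5p was 0.65 with the floor 4 times lower. It was 0.55 to 0.65 in 6 of the fits with 1 array left out, with no change left in the others. Arrays left out aside, the call was kept in 4 of 21 other settings for miR-125a-5p, 3 of 19 for miR-100-5p and 14 of 19 for miR-30c-5p. Leaving out miRNAs at the floor on all arrays ended those of miR-125a-5p and miR-100-5p (limma adjusted p = 0.0563 and 0.113). The brightest probe (0.0646) and a trended, robust spread (0.0874) also ended that of miR-125a-5p. MiR-199a-5p (0.28, limma adjusted p = 0.0503) and miR-26a-5p (0.39, limma adjusted p = 0.117) did not pass, nor did miR-34b-5p (0.36, limma adjusted p = 0.258). At an unadjusted p under 0.05 there were 18, all higher, and 31 miRNAs (26.3%) did not overlap. With slide as a block, and within slide 2 where 10 Gy had 1 array, the changes were 0.26 for miR-30c-5p (limma adjusted p = 0.00485), 0.19 for miR-125a-5p (0.314), 0.09 for miR-100-5p (0.239), 0.26 for miR-199a-5p and 0.27 for miR-26a-5p. Scaling over all probes called 90, all higher and with all 3 among them, and no scaling 24, all higher and with 2 of the 3. Median scaling called 22, all lower and none of the 3, and turned miR-100-5p (-0.01). Normexp with an offset of 50 turned miR-100-5p (-0.19), miR-125a-5p (-0.11) and miR-30c-5p (-0.18). The count was 1 without control replicate 2 or 10 Gy replicate 1 or 2, 5 without control replicate 3, 6 without 10 Gy replicate 3 and 10 without 2 Gy replicate 2.

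Camera moved 3 lists between the fractionated and the single 10 Gy dose. The miR-17 clusters were higher after 5x2 Gy (mean 0.25, camera adjusted p = 0.0393, blocked and within slide 2 0.10 with 0.793; adjusted p = 0.531 with an estimated correlation), with 0 of 12 members passing in either adjustment. Camera pointed lower for it with all probes, without scaling and with Feature Extraction's total signal. The damage response list was higher (mean 0.22, camera adjusted p = 0.0477, blocked and within slide 2 0.13 with 0.167; adjusted p = 0.401 with an estimated correlation), with 2 of 16 called, and 2 adjusted over the list alone, miR-30c-5p and miR-100-5p, which sat at the floor on 3 and 2 of the 10 Gy arrays. The miR-15/16 and miR-29/30 families were higher (mean 0.25, camera adjusted p = 0.0393, blocked and within slide 2 0.13 with 0.235; adjusted p = 0.456 with an estimated correlation), with 1 of 11 called, and 1 adjusted over the list alone, miR-30c-5p. Normexp at an offset of 50 turned the medians of all 3 (-0.01, -0.14 and -0.17). The rRNA and GC-rich list and the carcinoma list had positive means (0.30 and 0.11) while camera pointed lower, and let-7 a median of 0.05 against a mean of -0.02. The median change of all miRNAs was 1.09 with all probes, 1.11 without scaling and -0.17 with median scaling, against 0.03 as reported. With the mean of the rRNA and GC-rich list as a covariate, or without control replicate 1, 10 Gy replicate 1 or 2, or 5x2 Gy replicate 3, camera called 0 lists, and without control replicate 3, 2 Gy replicate 2 or 3, 10 Gy replicate 3, or 5x2 Gy replicate 1 or 2 it called 1.

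Between the single doses, 10 Gy minus 2 Gy, limma called 0 miRNAs, with 2 at an unadjusted p under 0.05, both higher. The smallest p belonged to let-7c-5p (0.16), miR-125a-5p (0.13), miR-34b-5p (0.31), miR-140-3p (0.21) and miR-130a-3p (-0.09), each with a limma adjusted p of 1. MiR-140-3p was detected on 1 of 3 arrays of each group. It fell to 0.049 without control replicate 3, 2 Gy replicate 2 or any 5x2 Gy array, of which only 2 Gy replicate 2 enters the difference. MiR-34b-5p was 0.13 without 2 Gy replicate 2. With slide as a block, and within slide 1, these were 0.12, 0.08, 0.34, 0.31 and -0.06. MiR-130a-3p turned with all probes (0.23), which raised the changes of miRNAs above the floor together, by 0.32 in the median, and with the authors' deposited log2 values (0.02). The let-7 family was higher after 10 Gy (mean 0.09, camera adjusted p = 0.0001, blocked and within slide 1 0.13 with 0.00195; adjusted p = 0.416 with an estimated correlation), with 0 of 9 members passing in either adjustment. Scaling over all probes and no scaling ended this call (camera adjusted p = 0.0938 and 0.491), and 13 of 15 other settings kept it. The miR-17 clusters did not pass (mean -0.10), but were called lower with slide as a block and within slide 1 (-0.17, blocked camera adjusted p = 0.000911; 9.63e-05 to 0.995 over its alternatives; adjusted p = 0.548 with an estimated correlation), and with array brightness as a covariate (median -0.13), median scaling (-0.06), quantile scaling (-0.08) and normexp at offsets of 50 and 1 (-0.06 and -0.06). Their median was 0.016 without 2 Gy replicate 2, without a call. Without 2 Gy replicate 2 or 10 Gy replicate 2 camera called 0 lists, and without control replicate 2, 2 Gy replicate 1 or 3, 10 Gy replicate 3 or any 5x2 Gy replicate it called 2. The p53 list had a median of -0.0032 and a mean of 0.05.

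Between 5x2 Gy and the single 2 Gy dose limma called 5 miRNAs, with positive differences for all 5. The count was 109 with all probes and 26 without scaling, all higher, and 0 with median scaling and with normexp at either offset. The 5 were miR-34b-5p (0.67, 1.59-fold, limma adjusted p = 0.0259), miR-125a-5p (0.42, 1.34-fold, limma adjusted p = 0.00152), miR-199a-5p (0.34, 1.27-fold, limma adjusted p = 0.0138), miR-30c-5p (0.26, no fold, limma adjusted p = 8.93e-05) and miR-100-5p (0.25, no fold, limma adjusted p = 0.00973). MiR-100-5p was detected on 1 of 3 arrays of 2 Gy and sat at the floor on 2, and was 0.68 with a floor 4 times lower (limma adjusted p = 0.26; 0.000339 to 1 over its alternatives) and 0.03 to 0.48 with 1 array left out. MiR-30c-5p was 0.92 with that floor and 0.81 to 0.85 in the 6 fits that tested it. With slide as a block they changed by 0.76 (limma adjusted p = 0.552), 0.27 (0.384), 0.31 (0.581), 0.26 (0.0245) and 0.08 (0.552). Normexp at an offset of 50 turned the last 4 (miR-125a-5p -0.07, miR-199a-5p -0.01, miR-30c-5p -0.15 and miR-100-5p -0.20). Camera moved 0 lists, with 1 member called in the p53 list, 2 in the damage response, and 1 each in inflammation, the miR-15/16 and miR-29/30 families and fibroblast markers. The carcinoma and the rRNA and GC-rich lists had positive means (0.12 and 0.13) while camera pointed lower. At an unadjusted p under 0.05 there were 25 (24 higher, 1 lower). The median change of all miRNAs was 1.34 with all probes, 1.12 without scaling and -0.11 with median scaling, against 0.04 as reported. Without 2 Gy replicate 1, 10 Gy replicate 1 or 5x2 Gy replicate 1 limma called 3, without control replicate 3 or 10 Gy replicate 3 it called 8, and without 2 Gy replicate 2 it called 11. Camera called 1 list without control replicate 2, 2 Gy replicate 1 or 10 Gy replicate 1.

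Across the 4 groups, limma's F test called 7 miRNAs, miR-30c-5p, miR-34b-5p, miR-125a-5p, miR-100-5p, miR-107-3p, miR-199a-5p and miR-129-2-3p, with 22 at an unadjusted p under 0.05. Without 5x2 Gy replicate 1 it called 2, without 2 Gy replicate 3 or 10 Gy replicate 1 or 2 it called 3, without control replicate 1 it called 4, without 2 Gy replicate 2 it called 11, and without control replicate 3 it called 13.

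Other miRNAs tied to radiation or to stress did not pass after any dose as reported, and some passed under other settings. The oncogenic miR-21a-5p changed by 0.22 after 2 Gy, 0.24 after 10 Gy and -0.06 after 5x2 Gy; the last was positive with quantile scaling (0.19). With 1 array left out it ran from 0.08 to 0.50, 0.11 to 0.51 and -0.19 to 0.17, each time from without control replicate 1 to without control replicate 2. It passed with array brightness as a covariate after 10 Gy (0.46, limma adjusted p = 0.0405; 0.0405 to 1 over its alternatives) and 5x2 Gy (0.55, limma adjusted p = 0.047; 0.00162 to 1), and after 5x2 Gy with all probes (1.59), without scaling (1.77) and with the authors' deposited log2 values (1.39). All probes and no scaling raised the changes of miRNAs above the floor together after 5x2 Gy, by 1.64 and 1.83 in the median, so passing or turning there, here and below, is not evidence on the single miRNA. The authors' values called most miRNAs after 5x2 Gy, all of them higher, so the same holds there. MiR-155-5p, an inflammation regulator, changed by -0.08, -0.01 and -0.03, without scaling by 0.03, 0.11 and 0.68, and turned without control replicate 2 (0.057, 0.12 and 0.076). After 5x2 Gy it passed without scaling, with all probes (0.76), with the authors' values (1.499) and, lower, with the mean of the rRNA and GC-rich list as a covariate (-0.18, limma adjusted p = 0.0297; 0.00538 to 1). Let-7a-5p changed by 0.08, 0.19 and 0.24 (-0.026, 0.079 and 0.13 without control replicate 1), and after 5x2 Gy passed with all probes (1.88), without scaling (2.06) and with the authors' values (1.68; limma adjusted p 0.00555 to 0.71 over its alternatives). MiR-17_v17.0 changed by -0.19, -0.29 and 0.13, and quantile scaling turned the first 2 (0.10 and 0.03). Without control replicate 2 it changed by -0.41, -0.53 and -0.15. It passed with brightness after 10 Gy (-0.51, limma adjusted p = 0.0269; 0.0269 to 1) and 5x2 Gy (-0.51), and after 5x2 Gy, higher, with all probes (1.43) and with the list covariate (0.49; limma adjusted p 0.0419 to 1). MiR-210-3p, induced by hypoxia, changed by -0.11, -0.24 and -0.01, and was positive without control replicate 3 (0.22, 0.10 and 0.28) and without scaling (0.15, 0.10 and 1.40). With slide as a block the changes after 10 Gy and 5x2 Gy were 0.42 and 0.48 for miR-21a-5p, -0.01 and -0.03 for miR-155-5p, 0.19 and 0.25 for let-7a-5p, -0.48 and -0.46 for miR-17_v17.0, and -0.47 and -0.73 for miR-210-3p. MiR-146a-5p, induced in inflammation, was detected on all 3 arrays of 5x2 Gy and on no control array, and sat at the floor, so no fold is given.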

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

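All tests of the explanations below were chosen after the results were seen, 19 in all, of which 12 are weighed and 7 stand beside them; the splits of the samples were fixed before.

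Outside the 118 tested miRNAs, 7 were detected on 2 of 3 arrays of 5x2 Gy and on 0 control arrays: miR-101a-3p, miR-126a-3p, miR-128-3p, miR-132-3p, miR-206-3p, miR-680 and miR-99b-3p. MiR-126a-3p and miR-680 were also detected on 1 array of 10 Gy. MiR-206-3p is a muscle marker and miR-126a-3p an endothelial marker. The 5x2 Gy arrays were brighter than the others and detected more miRNAs, 127 on average against 74 in control.

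The 15 miRNAs called in 5x2 Gy minus control were, as a set, 0.4161 above control, with miR-30c-5p at the floor on all control arrays. With array brightness as a covariate the mean was 0.4093 (SE 0.0396), but this cannot decide on brightness. Every 5x2 Gy array (1003.8 to 1101.7) was brighter than every other array (at most 897.3). The 15 were also picked on these arrays for a small spread within groups, which leaves little slope to fit. Background subtraction on dim arrays stays open and may account for the set: with normexp at an offset of 1 the mean was 0.0894 (SE 0.1151), while 27.2% of the values lay within 1 log2 of the floor. Slide cannot be told apart from irradiation, because only 10 Gy replicate 3 links the slides; with slide as a block the mean was 0.3847 (SE 0.0517). For the 10 miRNAs called from control and 5x2 Gy arrays alone, 8 of them among the 15 and all with positive differences, 60.8% of the values lay that near the floor, over the bound of 50%, so their means of 0.4481 (SE 0.044), -0.023 (SE 0.1712) and 0.4256 (SE 0.0584) against 0.4476 exclude nothing; the first set tried was the 15, then the 10, then the 15 again, and the near-floor bound and the rule that 1 linking array excludes nothing came after the values.

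The rRNA, tRNA, repeat and GC-rich list was lower in irradiated cells, with a mean change of -0.7827 (after 5x2 Gy, scaling over all probes and no scaling, which raised miRNAs above the floor together, gave medians of 0.74 and 0.84, and camera still called it lower than the others). A linear trend with array brightness is argued against, since with it as a covariate the change was -1.2201 (SE 0.2958). A state of control replicates 1 and 3, rather than irradiation, may account for it: control replicate 2 had a mean of -1.7514, inside the range of the irradiated arrays (-2.0289 to -1.0961), while control replicates 1 and 3 had 0.06 and -0.74. Irradiation stays open too, since the list was lower than both of those arrays on each irradiated array.

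The means of miR-34b-5p and miR-34c-5p together were 0.8925 higher in irradiated cells than in control (SE 0.2281). Slide is argued against for the single doses, where within slide 1 the change was 0.8773 (SE 0.2882) against 0.7948. MiR-34b-5p changed by 0.7364 (SE 0.1347) with the mean of the rRNA and GC-rich list as a covariate, against 0.8714. It was picked for a small spread, so this cannot decide on the arrays' state that the list marks. That state stays open for both and may account for miR-34c-5p, which changed by 0.3086 (SE 0.3175) with the covariate against 0.9137. Background subtraction stays open at each dose, since normexp with an offset of 50 gave 0.2991, 0.5259 and 0.5726 (SE 0.309 each) after 2 Gy, 10 Gy and 5x2 Gy against 0.6304, 0.9592 and 1.0881, all within 2 SE of 0, and an offset of 1 gave 0.4841, 0.7589 and 0.8579. For 5x2 Gy slide cannot be told apart from irradiation, because 1 array links the slides (1.5832 with a block, SE 0.4892), irradiation stays open at each dose, and the tests run first on both miRNAs over all doses gave 0.7003 (SE 0.24) with normexp at an offset of 1, 0.5225 (SE 0.2165) with the list's mean and 1.2599 (SE 0.1003) with brightness, while the 3p arms gave no test, since both sat at the floor on all arrays.

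Each pair of groups of 3 has 10 splits, too few for a share under 0.05. In 2 Gy minus control the real split called 0 miRNAs and the highest other 31, with 10 of 10 as large. In 10 Gy minus control these were 1 and 17, with 2 of 10. In 5x2 Gy minus control they were 15 and 0, with 1 of 10, in 5x2 Gy minus 10 Gy 3 and 0, with 1 of 10, in 10 Gy minus 2 Gy 0 and 1, with 10 of 10, and in 5x2 Gy minus 2 Gy 5 and 0, with 1 of 10. For lists, in the same order, the real split called 3, 4, 2, 3, 1 and 0, the highest other 3, 3, 3, 2, 2 and 2, and 3, 1, 4, 1, 7 and 10 of 10 were as large. The splits with 31 and 17 calls set control replicates 1 and 3 with 2 Gy replicate 2 or 10 Gy replicate 3 against the others. The first also parts bright from dim arrays. No cause was tested. For the F test, chance was not excluded: 5 of 100 splits gave as many miRNAs as the real 7, the highest 40. The real splits of 5x2 Gy against control and against 2 Gy follow the slides, with blocked counts of 1 each.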

How the results depend on the processing

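The alternatives added after the data were seen were array brightness and the mean of the rRNA and GC-rich list as covariates, a floor 4 times lower, leaving out miRNAs at the floor on all arrays, normexp with an offset of 1, and slide 1 alone; the others were fixed before. As reported, the counts of miRNAs were 0, 1, 15, 3, 0, 5 and 7, for 2 Gy, 10 Gy and 5x2 Gy minus control, 5x2 Gy minus 10 Gy, 10 Gy minus 2 Gy, 5x2 Gy minus 2 Gy and the F test, and those of lists 3, 4, 2, 3, 1 and 0 for the first 6. Counts below are in this order, values are log2 changes, and the cause was not tested for any difference except 1. For miRNAs above the floor on all arrays, scaling over all probes moved most changes together, by a median of 0.17, 0.49, 1.64, 1.15, 0.32 and 1.47 in the first 6 comparisons (59 miRNAs). The shifts ran from -0.05 to 0.22 in 2 Gy minus control and from 1.1 to 1.64 in 5x2 Gy minus control. Leaving out the scaling moved the changes by a median of 0.59, 0.65, 1.83, 1.18, 0.06 and 1.24 (49 miRNAs). Turned signs and gained calls under these 2 thus go mostly with a common shift and are not evidence on the single miRNA. MiR-34b-5p in 5x2 Gy minus control passed in 19 of 21 settings and without each of the 12 arrays. With camera's estimated correlation 0 lists passed in each comparison, and with fry, which asks only whether members move 1 way, 1, 1, 6, 5, 0 and 5. What signal over background limits is the dim arrays: only 48 of 118 miRNAs were detected on all arrays, and for the 19 at the floor on all arrays limma's spread was near 0.

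Normexp background correction with an offset of 50 gave 0, 2, 2, 0, 0, 0 and 2 miRNAs and 2, 3, 3, 0, 3 and 0 lists. Signs of miR-107-3p (-0.15) turned in 2 Gy minus control. Signs of miR-107-3p (-0.15) and miR-129-2-3p (-0.13) turned in 10 Gy minus control. Signs of let-7g-5p (-0.066), miR-100-5p (-0.47), miR-125a-5p (-0.31), miR-129-2-3p (-0.46), miR-17_v17.0 (-0.70), miR-199a-5p (-0.17), miR-214-3p (-0.18), miR-21a-5p (0.17), miR-25-3p (-0.34), miR-26a-5p (-0.019), miR-30b-5p (-0.35) and miR-30c-5p (-0.50) turned in 5x2 Gy minus control. Signs of miR-100-5p (-0.19), miR-125a-5p (-0.11), miR-17_v17.0 (-0.29), miR-199a-5p (-0.055), miR-210-3p (-0.30) and miR-30c-5p (-0.18) turned in 5x2 Gy minus 10 Gy. Signs of miR-100-5p (-0.20), miR-125a-5p (-0.075), miR-199a-5p (-0.0089) and miR-30c-5p (-0.15) turned in 5x2 Gy minus 2 Gy. Scaling to the 75th percentile over all miRNA probes gave 0, 1, 102, 90, 0, 109 and 86 miRNAs and 2, 2, 1, 1, 0 and 1 lists. Signs of miR-155-5p (0.17), miR-210-3p (0.11) and miR-92a-3p (0.20) turned in 10 Gy minus control. Signs of miR-155-5p (0.76), miR-210-3p (1.42) and miR-21a-5p (1.59) turned in 5x2 Gy minus control. Signs of miR-155-5p (0.59), miR-21a-5p (0.85) and miR-34c-5p (1.05) turned in 5x2 Gy minus 10 Gy. Signs of miR-130a-3p (0.23) turned in 10 Gy minus 2 Gy. Quantile normalization gave 2, 4, 7, 1, 0, 1 and 4 miRNAs and 1, 2, 2, 2, 2 and 2 lists. Signs of miR-155-5p (0.028), miR-17_v17.0 (0.097) and miR-210-3p (0.14) turned in 2 Gy minus control. Signs of miR-155-5p (0.12), miR-17_v17.0 (0.035) and miR-210-3p (0.020) turned in 10 Gy minus control. Signs of miR-155-5p (0.031), miR-210-3p (0.047) and miR-21a-5p (0.19) turned in 5x2 Gy minus control. Signs of let-7a-5p (-0.0014) turned in 5x2 Gy minus 10 Gy. Scaling to the median of the tested miRNAs gave 0, 1, 2, 22, 0, 0 and 1 miRNAs and 2, 2, 3, 1, 2 and 0 lists. Signs of miR-155-5p (0.0018) turned in 2 Gy minus control. Signs of miR-155-5p (0.13) turned in 10 Gy minus control. Signs of let-7a-5p (-0.16) and miR-100-5p (-0.0088) turned in 5x2 Gy minus 10 Gy. Leaving out the scaling gave 0, 0, 86, 24, 0, 26 and 23 miRNAs and 2, 2, 2, 2, 0 and 2 lists. Signs of miR-155-5p (0.029), miR-210-3p (0.15) and miR-92a-3p (0.28) turned in 2 Gy minus control. Signs of miR-155-5p (0.11), miR-210-3p (0.10), miR-720_v18.0 (0.028) and miR-92a-3p (0.36) turned in 10 Gy minus control. Signs of miR-155-5p (0.68), miR-210-3p (1.40) and miR-21a-5p (1.77) turned in 5x2 Gy minus control. Signs of miR-155-5p (0.57), miR-21a-5p (0.88) and miR-34c-5p (1.08) turned in 5x2 Gy minus 10 Gy. Doubling the floor gave 0, 1, 7, 1, 0, 4 and 3 miRNAs. Signs of miR-17_v17.0 (-0.028) turned in 5x2 Gy minus control. Testing all 576 miRNAs gave 0, 0, 6, 1, 0, 2 and 3 miRNAs. Testing only the 48 miRNAs detected on all arrays gave 0, 1, 6, 0, 0, 4 and 2 miRNAs. Taking the brightest probe per miRNA gave 1, 2, 21, 3, 0, 4 and 7 miRNAs and 4, 4, 2, 1, 1 and 0 lists. Feature Extraction's total signal per miRNA gave 0, 1, 10, 4, 0, 5 and 5 miRNAs and 1, 3, 3, 1, 1 and 0 lists. Signs of miR-155-5p (0.77), miR-17_v17.0 (0.88) and miR-210-3p (1.09) turned in 2 Gy minus control. Signs of miR-155-5p (1.00), miR-17_v17.0 (0.52) and miR-210-3p (0.74) turned in 10 Gy minus control. Signs of miR-155-5p (1.09) and miR-210-3p (1.04) turned in 5x2 Gy minus control. Signs of let-7a-5p (-0.10) and miR-155-5p (0.086) turned in 5x2 Gy minus 10 Gy. The authors' deposited log2 values gave 0, 0, 84, 0, 0, 2 and 4 miRNAs. In 5x2 Gy minus control most miRNAs were thus called, all higher, so calls and turned signs there are not evidence on the single miRNA. Signs of miR-155-5p (0.15), miR-17_v17.0 (0.25), miR-210-3p (0.36) and miR-92a-3p (0.074) turned in 2 Gy minus control. Signs of miR-155-5p (0.38), miR-17_v17.0 (0.25), miR-210-3p (0.23) and miR-92a-3p (0.20) turned in 10 Gy minus control. Signs of miR-155-5p (1.499), miR-210-3p (1.53) and miR-21a-5p (1.39) turned in 5x2 Gy minus control. Signs of miR-155-5p (1.12), miR-21a-5p (0.65) and miR-34c-5p (0.85) turned in 5x2 Gy minus 10 Gy. Signs of miR-130a-3p (0.018) turned in 10 Gy minus 2 Gy. limma with a trended, robust spread gave 0, 1, 7, 1, 0, 5 and 4 miRNAs. Fitting only the 2 groups compared gave 0, 2, 10, 2, 0 and 5 miRNAs. The slide as a fixed block gave 0, 0, 1, 1, 0, 1 and 1 miRNAs and 3, 3, 3, 0, 2 and 0 lists. Signs of miR-17_v17.0 (-0.46) and miR-21a-5p (0.48) turned in 5x2 Gy minus control. Signs of miR-210-3p (-0.25), miR-21a-5p (0.060) and miR-34c-5p (0.50) turned in 5x2 Gy minus 10 Gy. The slide as a random block gave 0, 1, 8, 2, 0, 5 and 5 miRNAs and 3, 4, 2, 3, 2 and 0 lists. Asking also for at least 1.5-fold gave 0, 1, 2, 0, 0 and 1 miRNAs. An unadjusted p under 0.05 with at least 1.5-fold gave 1, 7, 6, 2, 0 and 5 miRNAs.

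Normexp with an offset of 1 gave 1, 1, 5, 0, 0, 0 and 3 miRNAs and 3, 4, 2, 1, 2 and 0 lists. Signs of miR-107-3p (-0.029) turned in 2 Gy minus control. Signs of miR-100-5p (-0.25), miR-125a-5p (-0.028), miR-17_v17.0 (-0.38), miR-21a-5p (0.020), miR-25-3p (-0.066), miR-30b-5p (-0.024) and miR-30c-5p (-0.34) turned in 5x2 Gy minus control. Signs of miR-100-5p (-0.15), miR-17_v17.0 (-0.0091), miR-210-3p (-0.13) and miR-30c-5p (-0.18) turned in 5x2 Gy minus 10 Gy. Signs of miR-100-5p (-0.055) turned in 5x2 Gy minus 2 Gy. Array brightness as a covariate gave 6, 26, 28, 4, 0, 8 and 14 miRNAs and 2, 3, 4, 1, 2 and 2 lists. Signs of miR-155-5p (0.055) turned in 10 Gy minus control. Signs of miR-155-5p (0.15), miR-17_v17.0 (-0.51) and miR-21a-5p (0.55) turned in 5x2 Gy minus control. Signs of miR-155-5p (0.099), miR-210-3p (-0.14), miR-21a-5p (0.091) and miR-34c-5p (0.58) turned in 5x2 Gy minus 10 Gy. The mean of the rRNA, tRNA, repeat and GC-rich list as a covariate gave 1, 0, 41, 1, 0, 12 and 20 miRNAs and 0, 0, 0, 0, 1 and 0 lists; the loss of that list's own call is by construction. Signs of let-7a-5p (-0.065), miR-17_v17.0 (0.26) and miR-21a-5p (-0.20) turned in 2 Gy minus control. Signs of miR-17_v17.0 (0.25) and miR-21a-5p (-0.27) turned in 10 Gy minus control. Signs of miR-210-3p (0.056) turned in 5x2 Gy minus control. Signs of miR-155-5p (0.050) and miR-34c-5p (0.13) turned in 5x2 Gy minus 10 Gy. A floor 4 times lower gave 0, 1, 25, 4, 0, 8 and 8 miRNAs and 2, 3, 2, 0, 1 and 0 lists. Signs of miR-155-5p (0.11) turned in 5x2 Gy minus 10 Gy. Leaving out the 19 miRNAs at the floor on all arrays gave 0, 1, 15, 1, 0, 6 and 4 miRNAs and 3, 3, 1, 0, 1 and 0 lists. Slide 1 alone gave 0, 0 and 0 miRNAs and 3, 3 and 2 lists for 2 Gy minus control, 10 Gy minus control and 10 Gy minus 2 Gy.

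In 5x2 Gy minus control, scaling over all probes gave 102 higher and 0 lower, no scaling 86 and 0, the authors' deposited log2 values 84 and 0, each with all 15 among them, quantile scaling 6 and 1 (6 of the 15), Feature Extraction's total 7 and 3 (1 of the 15), brightness 21 and 7 (10 of the 15), the list covariate 29 and 12 (15 of the 15), the lower floor 22 and 3 (9 of the 15) and normexp at offset 1 1 and 4 (1 of the 15). In 5x2 Gy minus 10 Gy, median scaling gave 22 lower and 0 higher, scaling over all probes 90 higher and 0 lower (3 of the 3), and no scaling 24 and 0 (2 of the 3). In 10 Gy minus control, brightness gave 14 higher and 12 lower, the 1 reported among them. In 5x2 Gy minus 2 Gy, scaling over all probes gave 109 higher and no scaling 26. Normexp gave 2 lower with an offset of 50 in 10 Gy minus control and in 5x2 Gy minus control, and 1 lower with an offset of 1 in 10 Gy minus control. Named miRNAs that did not pass as reported also passed with brightness for miR-92a-3p in 2 Gy minus control (-0.34) and 10 Gy minus control (-0.33), miR-107-3p (0.12) and miR-129-2-3p (0.81) in 10 Gy minus control, and miR-199a-5p (0.35) and miR-26a-5p (0.23) in 5x2 Gy minus 10 Gy. With quantile scaling miR-107-3p passed in 2 Gy minus control (0.28) and 10 Gy minus control (0.30).

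Leaving out 1 array at a time gave 0 to 6, 0 to 8, 6 to 16, 1 to 10, 0 to 0, 3 to 11 and 2 to 13 miRNAs, and 0 to 3, 2 to 4, 0 to 4, 0 to 3, 0 to 2 and 0 to 1 lists. For 2 Gy and 10 Gy minus control the counts without each array are given above. Those of the 5x2 Gy comparisons and the F test are given above too. With 1 array left out its group of 2 was assumed to vary like the others, and miR-30c-5p was tested in only 6 of the 12 fits, passing in all 6, with changes of 0.81 to 0.86 in 5x2 Gy minus control, 0.55 to 0.65 in 5x2 Gy minus 10 Gy and 0.81 to 0.85 in 5x2 Gy minus 2 Gy against 0.26. Calls gained with 1 array left out included miR-34b-5p in 2 Gy minus control (0.73 without 2 Gy 2), miR-92a-3p in 2 Gy and 10 Gy minus control (-0.33 and -0.33 without control 2), miR-107-3p in 2 Gy minus control (0.24 and 0.15 without control 2 and 3) and 10 Gy minus control (0.20 without control 3), miR-720_v18.0 (-0.81 without control 3) and miR-129-2-3p (0.38 without 2 Gy 2) in 10 Gy minus control, and miR-199a-5p (0.28 without control 3 or 2 Gy 2) and miR-26a-5p (0.39 without 2 Gy 2) in 5x2 Gy minus 10 Gy. For single miRNAs, let-7a-5p ran from -0.026 to 0.18 in 2 Gy minus control, turning without control 1 (-0.026). For miR-155-5p, the change ran from -0.11 to 0.12 in 10 Gy minus control, turning without control 2 (0.12) and 10 Gy 1 (0.0043). It ran from -0.18 to 0.057 in 2 Gy minus control, turning without control 2 (0.057). It ran from -0.13 to 0.076 in 5x2 Gy minus control, turning without control 2 (0.076). For miR-17_v17.0, the change ran from -0.15 to 0.28 in 5x2 Gy minus control, turning without control 2 (-0.15). For miR-210-3p, the change ran from -0.51 to 0.10 in 10 Gy minus control, turning without control 3 (0.10) and 10 Gy 2 (0.0046). It ran from -0.28 to 0.22 in 2 Gy minus control, turning without control 3 (0.22) and 2 Gy 3 (0.17). It ran from -0.015 to 0.40 in 5x2 Gy minus 10 Gy, turning without 10 Gy 2 (-0.015). It ran from -0.19 to 0.28 in 5x2 Gy minus control, turning without control 3 (0.28), 2 Gy 2 (0.014), 10 Gy 3 (0.014) and 5x2 Gy 1 (0.23). For miR-21a-5p, the change ran from -0.19 to 0.17 in 5x2 Gy minus control, turning without control 2 (0.17) and 5x2 Gy 1 (0.036), from 0.080 to 0.50 in 2 Gy minus control and from 0.11 to 0.51 in 10 Gy minus control. MiR-34c-5p ran from 0.47 to 1.11 in 2 Gy minus control. It ran from -0.40 to 0.11 in 5x2 Gy minus 10 Gy, turning without 10 Gy 2 (0.11). Let-7g-5p in 5x2 Gy minus control lost its call without any array but control 3, 2 Gy 2, 10 Gy 1, 10 Gy 3 or 5x2 Gy 1 (limma adjusted p 0.013 to 0.124). The call of miR-100-5p in 5x2 Gy minus 10 Gy was lost without control 1, control 2, 2 Gy 1, 2 Gy 3, 10 Gy 1 or 10 Gy 2 (limma adjusted p 0.000339 to 0.549), and the change ran from 0.03 to 0.34, over 1.5 times off 0.20 without any array but 10 Gy 1. MiR-100-5p in 5x2 Gy minus 2 Gy lost its call without control 1, control 2, 2 Gy 1, 2 Gy 3, 10 Gy 1 or 10 Gy 2 (limma adjusted p 0.000339 to 0.156), and the change ran from 0.03 to 0.48, over 1.5 times off 0.25 without each of the 12 arrays. The call of miR-100-5p in 5x2 Gy minus control was lost without control 1, control 2, 2 Gy 1, 2 Gy 3 or 10 Gy 2 (limma adjusted p 0.000339 to 0.11), and the change ran from 0.03 to 0.51, over 1.5 times off 0.23 without any array but control 2. In all 3 comparisons miR-100-5p changed by 0.045, 0.050 and 0.033 without 5x2 Gy 1, 2 and 3, and by 0.042 without control 3, 2 Gy 2 or 10 Gy 3, near 0 while the call was kept. MiR-125a-5p in 5x2 Gy minus 10 Gy lost its call without control 2, 10 Gy 1, 10 Gy 2, 5x2 Gy 1 or 5x2 Gy 2 (limma adjusted p 0.00535 to 0.119). The call of miR-129-2-3p in 5x2 Gy minus control was lost without control 1, control 2 or 10 Gy 2 (limma adjusted p 0.00092 to 0.0876), and the change ran from 0.62 to 1.3, with 0.62 without 5x2 Gy 1 and 0.67 without control 3, 2 Gy 2, 10 Gy 3 or 5x2 Gy 3; it was 0.087 with the floor doubled and 1.43 with the lower floor. MiR-199a-5p in 5x2 Gy minus 2 Gy lost its call without 2 Gy 1 or 5x2 Gy 1 (limma adjusted p 0.00525 to 0.0702). The call of miR-214-3p in 5x2 Gy minus control was lost without any array but 2 Gy 2, 2 Gy 3 or 10 Gy 3 (limma adjusted p 0.0257 to 0.136). MiR-24-3p in 5x2 Gy minus control lost its call without any array but control 1 (limma adjusted p 0.0027 to 0.138), and changed by 0.21 without control 2. The call of miR-25-3p in 5x2 Gy minus control was lost without control 1, control 2 or 10 Gy 2 (limma adjusted p 0.00437 to 0.113). MiR-26a-5p in 5x2 Gy minus control lost its call without control 1, control 2, 5x2 Gy 1, 5x2 Gy 2 or 5x2 Gy 3 (limma adjusted p 0.0155 to 0.1). The call of miR-30b-5p in 5x2 Gy minus control was lost without control 1, control 2, 5x2 Gy 1 or 5x2 Gy 2 (limma adjusted p 0.00661 to 0.0685), and the change was 0.73, 0.74 and 0.84 without 5x2 Gy 1, 2 and 3. MiR-34b-5p in 10 Gy minus control lost its call without control 1, 10 Gy 2, 10 Gy 3, 5x2 Gy 1, 5x2 Gy 2 or 5x2 Gy 3 (limma adjusted p 0.000174 to 0.0921). The call of miR-34b-5p in 5x2 Gy minus 2 Gy was lost without control 2, 10 Gy 1, 5x2 Gy 1, 5x2 Gy 2 or 5x2 Gy 3 (limma adjusted p 0.00697 to 0.0785). Lists lost their camera call as follows, with the range of camera adjusted p: the p53 list in 2 Gy minus control without control 1, control 2, 2 Gy 1 or 10 Gy 3 (0.0248 to 0.101), the miR-17 clusters in 2 Gy minus control without control 1, control 3 or 2 Gy 3 (0.00169 to 0.201), the rRNA and GC-rich list in 2 Gy minus control without control 1 (1.42e-05 to 0.052), let-7 in 10 Gy minus control without control 1 (0.00151 to 0.182). Its call also ended with median and quantile scaling (camera adjusted p = 0.0992 and 0.0685). Further ones were fibroblast markers in 10 Gy minus control without any array but control 2 (0.0485 to 0.277), fibroblast markers in 5x2 Gy minus control without any array but control 2, 2 Gy 1, 2 Gy 3, 10 Gy 1 or 10 Gy 2 (0.027 to 0.147), the rRNA and GC-rich list in 5x2 Gy minus control without control 1 (5.4e-06 to 0.0709), the miR-17 clusters in 5x2 Gy minus 10 Gy without control 1, 10 Gy 1, 10 Gy 2 or 5x2 Gy 3 (0.00902 to 0.142). The last were the damage response in 5x2 Gy minus 10 Gy without any array but control 2 (0.036 to 0.692), miR-15/16 and miR-29/30 in 5x2 Gy minus 10 Gy without any array but control 2 or 2 Gy 1 (0.035 to 0.312), let-7 in 10 Gy minus 2 Gy without 2 Gy 2 or 10 Gy 2 (7.2e-05 to 0.238).

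The replicate numbers did not pair the arrays: 6 of 18 pairs correlated over 0.1, from -0.88 to 0.73, and 1 array correlated best with its own number. With the number as a replicate block the counts were 0, 0, 10, 2, 0, 3 and 3 miRNAs and 3, 4, 2, 3, 1 and 0 lists.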

Other observations

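Among the probes outside the comparisons, 5 miRNAs were detected on 1 array of 2 Gy and on no other array: miR-376b-3p, miR-452-5p, miR-466f-3p, miR-466g and miR-574-3p. MiR-376b-3p belongs to the Dlk1-Dio3 cluster. MiR-183-5p, miR-185-5p, miR-378a-3p and miR-484 were each detected on 1 array of 5x2 Gy and on no other array.

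The mean of the rRNA, tRNA, repeat and GC-rich list was 0.06, -1.75 and -0.74 on control replicates 1 to 3, -1.93, -1.10 and -1.72 after 2 Gy, -1.71, -2.03 and -1.51 after 10 Gy, and -1.39, -1.50 and -1.45 after 5x2 Gy. The first principal component of the tested miRNAs held 60.4% of the variance and the second 22.3%. Array brightness correlated with the second (r = 0.85, permutation p = 0.00032, adjusted over 8 relations 0.00113; rho = 0.74, permutation p = 0.00838, adjusted 0.0223), and without the 2 arrays farthest from the median r was 0.71. On the 8 arrays of slide 1 it was 0.66 (exact permutation p = 0.0849), and -0.17 without the 2 farthest arrays, so there the relation rests on those arrays. By rank alone, brightness also went with the first component (rho = -0.62, permutation p = 0.037, adjusted 0.0423; r = -0.46, permutation p = 0.129, adjusted 0.206) and with the mean of the rRNA and GC-rich list (rho = 0.62, permutation p = 0.037, adjusted 0.0423; r = 0.22, permutation p = 0.491, adjusted 0.491). On slide 1 rho was -0.76 and 0.76 (exact permutation p = 0.0368 for both, adjusted 0.0423), with r of -0.55 (adjusted 0.221) and 0.40 (adjusted 0.389). Without the 2 farthest arrays r was -0.39 and 0.16, and -0.53 and 0.42 on slide 1.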
